A study of Rattus norvegicus with 16 samples.

How the data were processed

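Total RNA from the pontine nuclei of rats had been extracted with Trizol, turned into biotin-labelled cRNA and hybridised to 16 Affymetrix rat arrays, 1 array per condition: 9 lesion-side arrays (saline, lysolecithin or transection on days 4, 10 and 37), 6 contralateral arrays (the 3 interventions on days 10 and 37) and 1 healthy control. How many animals each array stood for was not used here. The submitters' processing notes name MAS5, with no version. The deposited signal is a linear MAS5 intensity per probe set, scaled by the authors on each array to a common trimmed mean. Per the file headers each probe set also has a detection call and a detection p-value, used as deposited. The deposited series value table holds log2-like values for 7773 probe sets. How it was made is not stated. For probe sets with a mean log2 signal over 9, each probe set's mean across arrays was subtracted from the table and from the log2 signals. The deviations in each column correlated with those of its own array at 0.814 to 0.968 and of another array at no more than 0.495. The table served as an alternative source.

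The analysis used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The models, alternatives, gene lists and the rule for naming genes were chosen before the data were examined. Signals were transformed as log2(signal + 16) with the deposited scaling kept, and probe sets called Present on at least 3 of the 16 arrays were tested: 4413, of which 3636 had 1 gene symbol, for 2713 genes. In the platform annotation 6283 probe sets had 1 symbol, 280 several and 2236 none. The reference gene table served for names alone. Correlations between arrays and the beta-actin and GAPDH 3′/5′ signal ratios were computed per array.

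Each comparison was a linear model in limma with moderated statistics, an intensity trend and Benjamini-Hochberg adjustment over the 4413 probe sets, with a threshold of 0.05. Comparisons with controls used all 16 arrays in 4 groups (12 residual degrees of freedom). Comparisons between interventions or days used the 9 lesion-side arrays with intervention and day as terms (4 residual degrees of freedom). The side comparison used 6 pairs with the pair as a block (5 residual degrees of freedom). With 1 array per condition the days stood in for replicates, so the errors hold differences between conditions as well as between arrays. In the comparisons with controls, which have no day term, they include differences between days. No paired analysis was possible for day 4 because it has no contralateral array. Single pairs of arrays were described by their log2 ratios without a test, with the healthy array in place of a contralateral one on day 4.

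Named genes followed this rule: in each comparison, among probe sets with 1 symbol past the threshold that moved the same way on every day or pair, the 12 largest rises and 12 largest falls, with the probe set of smallest p for each gene. Where fewer than 5 passed, the 6 highest and 6 lowest differences among the 100 smallest p-values could be named as values that did not pass. For the lists described in the text, members past the threshold when adjusted over the list alone were named. For single pairs the 5 highest and 5 lowest ratios were eligible, among probe sets Present on both arrays with a signal over 200 on the higher one. Some eligible genes that did not pass are left unnamed in the text. Other probe sets of Hspb1 and Kctd13, and the genes described on contralateral arrays alone, were chosen after their values were seen. Where a probe set was called Absent on every array of its dimmer group and Present on an array of the other, its fold is given as "at least", computed with each dimmer signal raised to the lowest signal called Present on that array where it was below it. That lowest signal was 0 to 60.1 among the arrays. Where the dimmer signals lay above it, the "at least" fold equals the plain difference. It takes no account of the SE and is not a confidence bound.

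Of 28 gene lists written in advance, the 20 with at least 5 tested members were tested in 10 comparisons. The other 8 were left untested: blood cells with 4 tested members, monoaminergic, cholinergic and cerebellar neurons or cells with 3 each, Schwann cells with 2, choroid plexus and forebrain neurons with 1 each and sex-linked genes with 0. Lists were tested with the brightest probe set of each gene, so a gene's value within a list can differ from its value as a named gene. The rotation test fry in limma was run for a shift in 1 direction and for change in either direction (mixed), adjusted over the 200 tests of each kind, and camera with a preset correlation of 0.01 or an estimated correlation was run as an alternative. In single pairs, list medians were placed among 10000 random lists drawn in 20 bins of expression. One list entry written for transferrin had been matched to Trh through a synonym, and this match was dropped after values had been seen.

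The models were tested on simulated data. Of 100 probe sets changed 2-fold, 93 to 100 were recovered in the 4 designs tried, and of 100 changed 4-fold, 99 or 100, with 4 to 12 false calls among 4413. With no change simulated, 4.33% to 5% of directional list tests and 4.17% to 7.33% of mixed list tests had a p under 0.05, and 2.17% to 2.83% of mixed tests had a p under 0.01, so the mixed test was somewhat liberal. Of 3 lists moved in simulation 3 were recovered, with 0 of 13 others past the threshold. The simulated noise was independent between probe sets, with no correlation between genes and no differences between days or pairs. These rates therefore do not cover correlation between genes on the real arrays.

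The alternatives were quantile normalization, a pseudocount of 1 or 64, no detection filter or Present calls on at least 8 arrays, no intensity trend, array weights, the series value table, other sets of controls, no day, pair or intervention term, differences of lesion-minus-contralateral differences, and each array left out in turn.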

Results

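Gene expression was measured in the pontine nuclei of rats, brainstem cell groups whose neurons send their axons to the cerebellum, after an injury to those axons at a distance from the cell bodies. The axons had been exposed to saline, exposed to lysolecithin, a detergent-like lipid that strips myelin, or transected, and the nuclei were collected on days 4, 10 and 37. The series title places the question in the response of the neuron to demyelination and to transection. Each of the 16 Affymetrix arrays was hybridised with biotin-labelled RNA from 1 condition: 9 arrays came from the lesion side (3 interventions on 3 days), 6 from the contralateral side (3 interventions on days 10 and 37) and 1 from a healthy control. No condition had a second array, so the 3 days of an intervention stood in for replicates, and every SE and p-value below measures the spread between arrays of different conditions. In the comparisons with controls that spread includes the differences between days. The number of arrays limits the precision. Of the probe sets on each array, between 39.9% (healthy control) and 47.1% (saline day 37, lesion side) were called Present, and 4413 probe sets, standing for 2713 named genes, were tested. The beta-actin 3′/5′ signal ratio, a sign of RNA integrity, was 1.41 to 1.68 on the saline lesion-side arrays, at most 1.44 after lysolecithin and 1.07 to 1.42 after transection. The same ratio of GAPDH was 1.26 on the healthy control and 1.03 to 1.23 on the other arrays. Arrays other than the healthy control correlated at r = 0.953 to 0.988 across probe sets, and the healthy control correlated with them at 0.914 to 0.950.

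Transection was first set against the 7 control arrays, 6 contralateral and 1 healthy, to ask what changed in the cell bodies of cut axons. Jun, a transcription factor induced in injured neurons (probe set rc_AI175959_at), rose 2.26-fold on the lesion side, from 9.02 ± 0.17 (SD, n = 7) to 10.2 ± 0.62 (SD, n = 3) in log2 signal (log2 difference 1.18, SE 0.19; limma adjusted p = 0.044; higher on 3 of 3 days). Of the 21 measured regeneration-associated genes, 7 rose and 0 fell when adjusted over the list alone, and 1 (Jun) when adjusted over all probe sets. The injury transcription factor Atf3 was 4.19-fold higher (SE of log2 0.42), the peptidase Ecel1 2.85-fold (SE 0.32), the growth-arrest gene Gadd45a 2.76-fold (SE 0.29) and the growth-cone protein Gap43 2.11-fold (SE 0.23), each on 3 of 3 days and each with a limma adjusted p of 0.0736 over all probe sets. The neuropeptide precursor Adcyap1 (PACAP) and the neurotrophic receptor Ret, 1.66-fold and 1.63-fold higher, completed the 7. The stress factor Ddit3 (CHOP) rose 2.73-fold when adjusted over the list of 14 apoptosis and cell stress genes alone. Of 21 synaptic vesicle and release genes 18 were lower, with a median log2 difference of -0.23. Sncb, Cplx1, Vamp2 and Syp fell and Syt4 rose 1.60-fold when adjusted over the list alone. The neurofilament gene Nefl fell by 0.33 on the log2 scale when adjusted over the 6 pan-neuronal genes alone, and the thyrotropin-releasing hormone precursor Trh was 4.73-fold higher (SE of log2 0.51) with a limma adjusted p of 0.0948.

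In the same comparison, the neurofilament gene Ina was lower by a log2 difference of -0.88 (SE 0.19) and Cited2, a transcriptional co-regulator, by -1.09 (SE 0.27). Neither passed the threshold (limma adjusted p 0.0736 and 0.147). As a set that changed in either direction, the regeneration-associated genes (adjusted p = 0.00342), the release genes (0.0125), the cytoskeletal and axonal transport genes (0.0297) and the stress genes (0.0312) passed the mixed rotation test fry in limma. The directional fry test passed for none, with adjusted p of 0.269 and 0.326 for the first 2 lists. With camera the regeneration list was higher (adjusted p = 0.0011) and the release list lower (0.00798), and both had adjusted p = 0.696 with an estimated correlation. Camera did not pass for the cytoskeletal (0.424, and 0.801 with an estimated correlation) and stress lists (0.435 and 0.776). The receptor genes were lower in 20 of 24 cases with camera (adjusted p = 0.0193, and 0.696 with an estimated correlation). In all, 1 of 4413 probe sets passed with limma and 487 had an unadjusted p under 0.05. The call of Jun ended without the detection filter, without the intensity trend, with array weights, against contralateral arrays alone, against their own contralateral arrays in pairs, on days 10 and 37 alone (2 probe sets past the threshold) and when any single array was left out other than the day 37 lesion-side arrays of lysolecithin (3 probe sets past the threshold) or transection (64, 40 higher and 24 lower). 2 others passed without the transection day 4 array.

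The day course of these genes is shown in the plot of injury-response genes. Atf3 on the lesion side stood at a log2 signal of 10.9 on day 4, 11.3 on day 10 and 8.65 on day 37 after transection, at 9.61, 9.92 and 8.55 after lysolecithin and at 8.21, 8.26 and 8.29 after saline, beside 7.83 to 8.96 on the 7 control arrays. Jun after transection stood at 10.5, 10.6 and 9.48, beside 8.84 to 9.26 on the controls. Trh after transection went from 12.2 and 12.5 on days 4 and 10 to 9.70 on day 37, beside 8.62 to 10.5 on the controls.

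**Figure D1:**
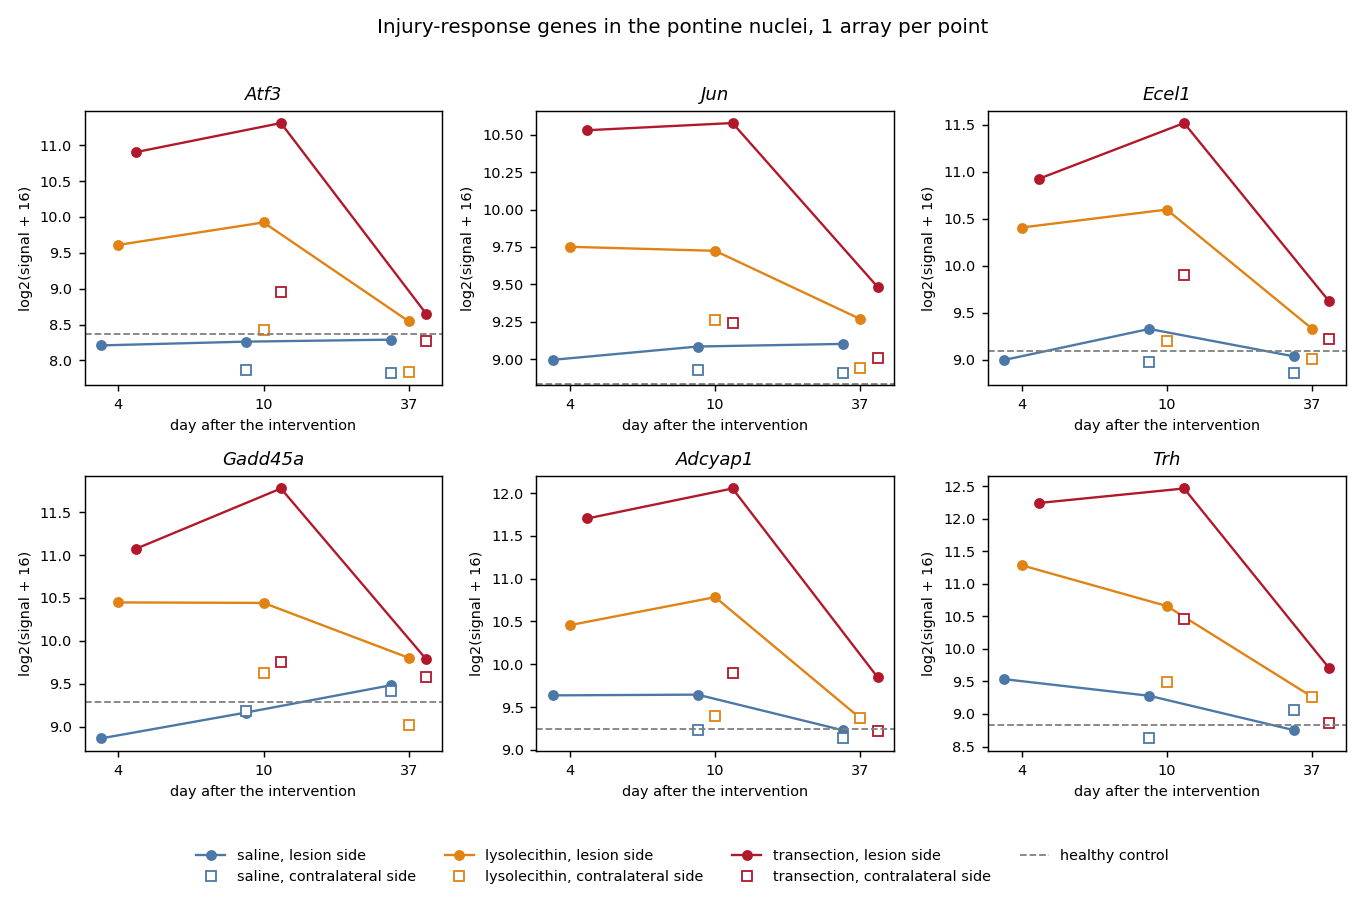
Log2(signal + 16) of 6 genes on the 16 arrays against the day after the intervention; filled circles joined by lines are lesion-side arrays, open squares contralateral arrays, the dashed line the healthy control, with 1 array per point. After transection Atf3 stands at 10.9 and 11.3 on days 4 and 10 and at 8.65 on day 37.

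Lysolecithin against the same 7 control arrays gave the corresponding view of demyelinated axons, and no probe set passed. Among the high values, Gadd45a was 2.32-fold higher (SE of log2 0.40), Atf3 2.20-fold (SE 0.42), Ecel1 1.91-fold (SE 0.32), the p53-responsive gene Ccng1 1.59-fold (SE 0.20) and the smooth muscle protein Tagln 1.90-fold (SE 0.32; Present on 0 of the controls), each on 3 of 3 days and each with a limma adjusted p of 0.972. On the low side stood Acaa1b, an enzyme of peroxisomal fatty acid oxidation, with a log2 difference of -0.71 (SE 0.22), and the lysosomal membrane gene Lamp1 with -0.59 (SE 0.23). Of the 21 regeneration-associated genes 16 were higher, with a median of 0.16. Camera placed the list above other genes (adjusted p = 0.00843), with adjusted p = 0.696 with an estimated correlation and 0.429 in the directional rotation test. The 12 measured oligodendrocyte genes, markers of the myelinating cells, had a median of 0.08 with 9 of 12 higher (adjusted p = 0.890 in the limma fry mixed test). With limma 0 of 4413 probe sets passed and 205 had an unadjusted p under 0.05. The same count of 0 was found under every other setting and with any single array left out.

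Saline lesion-side arrays against the 7 controls gave the background of the procedure itself, and again no probe set passed. When adjusted over the list alone, the astrocyte glutamate transporter Slc1a2 (log2 difference -1.03, SE 0.19) and the protease inhibitor Timp1 (-0.81, SE 0.20) fell among 17 astrocyte genes, Bcl2 (-0.55, SE 0.13) among 14 stress genes, the NMDA receptor subunit Grin2b (-0.50, SE 0.13) among 24 receptor genes, Cd14 (-0.67, SE 0.20) among 11 microglial genes and Igfbp2 (-0.56, SE 0.17) among 10 meningeal genes. Igfbp2 was called Present on 0 of 3 saline and 2 of 7 control arrays, so its size depends on signals near background. Timp1 was called Present on 0 of 3 saline and 3 of 7 control arrays, so its size depends on signals near background as well. The cholesterol synthesis gene Cyp51 was 1.54-fold higher (SE of log2 0.11) and the fatty acid synthesis gene Acly was higher by 0.58 (SE 0.18), with limma adjusted p of 0.0721 and 0.329. Of 32 respiratory chain genes 29 were higher, with a median of 0.18 (camera adjusted p = 0.000339, and 0.696 with an estimated correlation). Of 16 MHC and interferon genes 13 were lower, with a median of -0.33 (camera adjusted p = 0.00653, and 0.696 with an estimated correlation). The 7 controls include the contralateral arrays after lysolecithin and transection, where the medians of this list were 0.55 and 0.33 above the saline contralateral arrays. Against its own contralateral array, saline had medians of -0.08 on day 10 and 0.06 on day 37 for this list. The mixed limma fry test passed for the astrocyte list (adjusted p = 0.0297) and the receptor list (0.0452), the latter with a median of 0.02 and a mean of -0.01. The receptor call ended with quantile normalization (limma fry mixed adjusted p = 0.0899). Neither list passed with camera (adjusted p = 0.121 and 0.807, and 0.696 and 0.942 with an estimated correlation). One probe set named Kctd13 (rc_AA859966_i_at) had a log2 difference of -4.43 (SE 0.83; limma adjusted p = 0.0721), while the others of that gene differed by -0.06 and -0.30. The beta-actin 3′/5′ ratio was 1.41 to 1.68 on these arrays and 1.04 to 1.53 on the controls. With limma 0 probe sets passed and 549 had an unadjusted p under 0.05. The count was 4 with array weights and 2 from the series value table, and it was 1 without the saline day 10, saline day 37, lysolecithin day 37 or transection day 4 lesion-side array.

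Transection and saline were compared within the lesion side with day as a term, which set cut axons against the saline procedure. Of the named genes past the threshold, 16 were higher after transection and 6 lower. Trh was 4.86-fold higher after transection (SE of log2 0.32; limma adjusted p = 0.0315), Atf3 4.09-fold (SE 0.37; 0.0358), Gadd45a 3.26-fold (SE 0.33; 0.0421), Adcyap1 3.24-fold (SE 0.26; 0.0315), Ecel1 2.97-fold (SE 0.25; 0.0315) and Jun 2.20-fold (SE 0.20; 0.0358). The small heat shock protein Hspb1 (2.29-fold, SE 0.19), the small proline-rich protein Sprr1a (1.94-fold, SE 0.17), the MHC class II invariant chain Cd74 and the vasopressin precursor Avp (1.92-fold, SE 0.18) rose as well. Complement C3, Absent on all 3 saline arrays, rose at least 1.89-fold. Among the 6 genes that fell were the neurofilament gene Ina (log2 difference -0.78, SE 0.13; limma adjusted p = 0.0338), beta-synuclein Sncb (-0.75, SE 0.15; 0.049), the kinase gene Matk (-0.85, SE 0.15; 0.0358), Cited2 (-0.62, SE 0.11; 0.0358), Iqsec1 (-0.58, SE 0.11; 0.0457) and the respiratory chain subunit Ndufb8 (-0.53, SE 0.10; 0.0433). Each of these genes moved the same way on 3 of 3 days. Cd74 was called Present on 1 of 3 transection and 0 of 3 saline arrays, so no size is given for it. Matk was called Present on 0 of 3 and 3 of 3, so its size depends on signals near background. A brighter Hspb1 probe set (rc_AI176658_s_at) differed by 0.40 and did not pass.

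By list, 8 of 21 regeneration-associated genes rose when adjusted over the list alone and 6 when adjusted over all probe sets, with 17 of 21 higher and a median of 0.35 (limma fry mixed adjusted p = 0.0524; camera 0.000171, and adjusted p = 0.696 with an estimated correlation). Ddit3 rose 2.36-fold among 14 stress genes, adjusted over the list alone. Of 20 cytoskeletal and transport genes Map1b rose 1.89-fold while Ina, Dync1i1, Nefm and Nefl fell, adjusted over the list alone (limma fry mixed adjusted p = 0.0312; camera 0.336, and 0.799 with an estimated correlation). Among 21 release genes Syt4 rose 1.74-fold and Sncb, Sv2b, Rab3a and Syp fell, adjusted over the list alone (limma fry mixed adjusted p = 0.123). Among 24 receptor genes Grin1 rose 1.53-fold and Grm2, Grik1, Glra2 and Gabrb2 fell, adjusted over the list alone (limma fry mixed adjusted p = 0.0355; camera 0.187, and 0.813 with an estimated correlation). On the saline day 4 array a probe set each of Map1b, Grin1 and Avp was 3.97-fold, 3.76-fold and 3.60-fold below the healthy control. Whether low saline values carry their rises was not tested. Of 32 respiratory chain genes 30 were lower, with a median of -0.22, beside beta-actin 3′/5′ ratios of 1.07 to 1.42 after transection and 1.41 to 1.68 after saline and GAPDH ratios of 1.07 to 1.19 and 1.09 to 1.16. Ndufb3, Ndufa8, Cox7b and Ndufb8 fell when adjusted over the list alone (limma fry mixed adjusted p = 0.0452; camera 9.37e-07, and adjusted p = 0.696 with an estimated correlation). Astrocyte genes were higher in 14 of 17 cases, with a median of 0.32 (limma fry mixed adjusted p = 0.0312; camera 0.00272, and adjusted p = 0.696 with an estimated correlation): the gap junction gene Gja1 rose 2.48-fold, the water channel Aqp4 2.10-fold, Slc1a2 1.54-fold and Clu 1.42-fold, adjusted over the list alone. Timp1 passed as well but was called Present on 0 of the 6 arrays, so it is not counted as a rise. Of 16 MHC and interferon genes 14 were higher and Cd74, Psme1 and RT1-Da rose, and of 11 microglial genes 10 were higher and Lgals3 (2.13-fold) and Cd53 (1.51-fold) rose, adjusted over the list alone (limma fry mixed adjusted p = 0.0312 and 0.0422; camera adjusted p = 0.00272 and 0.00599, and 0.696 for both with an estimated correlation). Against the 7 controls the medians after transection were -0.15 (MHC), 0.12 (microglia), 0.13 (astrocytes) and -0.05 (respiratory chain). None of these 4 passed (limma fry mixed adjusted p = 0.741, 0.890, 0.158 and 0.741), with the contralateral arrays described above among these controls. Cholesterol synthesis genes were lower in 11 of 14 cases, with a median of -0.20 (limma fry mixed adjusted p = 0.00599; directional fry 0.271, camera 0.0739, and 0.696 with an estimated correlation), and the chaperone list, with 9 of 23 genes higher, also passed the mixed test (limma fry mixed adjusted p = 0.0312; camera 0.762, and 0.942 with an estimated correlation), with 0 members of either list past the threshold over the list alone.

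For transection against saline, 32 probe sets passed with limma, 24 higher and 8 lower, standing for 22 named genes (16 higher, 6 lower) and 3 probe sets with no symbol. 748 had an unadjusted p under 0.05. Kctd13 was among them at 24.8-fold, from the single probe set that was low on saline arrays. The count fell to 14 with quantile normalization and to 0 without the detection filter, the intensity trend or the day term. It was 0 as a difference of lesion-minus-contralateral differences, in which Hspb1, Cd74, C3, Psme1, Lgals3, RT1-Da, Cd53 and Timp1 turned to lower values after transection. It was 0 without the day 4 or day 10 saline or the day 4 lysolecithin array. It was 1, 5 and 7 without the transection day 10, transection day 4 and lysolecithin day 10 arrays, and 55 and 56 without the transection and the saline day 37 arrays.

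Transection and lysolecithin were compared on the lesion side to separate cut from demyelinated axons. Lower after transection were Rab3a, a GTPase of synaptic vesicles, by a log2 difference of -1.10 (SE 0.18; limma adjusted p = 0.0476), the vesicle protein Syt11 by -0.92 (SE 0.18; 0.0483), complexin Cplx1 by -0.70 (SE 0.13; 0.048), Ina by -0.88 (SE 0.13; 0.036) and the potassium channel genes Kcna1 and Kcnc4 by -0.94 (SE 0.18; 0.048) and -0.78 (SE 0.13; 0.0476). The neuronal death inhibitor Faim2 (-0.83, SE 0.11; 0.022), the anti-apoptotic gene Bcl2l1 (-0.96, SE 0.15; 0.0416), the proton pump subunit Atp6v0a1 (-0.93, SE 0.15; 0.0416), the endocytic gene Epn1 (-0.72, SE 0.13; 0.048), Snn (-0.75, SE 0.13; 0.048) and the transcription co-regulator Lbh (-1.13, SE 0.15; 0.022) were also lower than after lysolecithin, and Dab2, Absent on all 3 transection arrays, was at least 1.90-fold lower. Syt11, Cplx1 and Bcl2l1 were higher after lysolecithin than after saline, as given below. Their differences here therefore do not show a fall after transection alone. Of the genes named here as lower, Ina alone also passed as lower against saline over all probe sets, and Rab3a did so over its list alone. For the rest, a fall after transection was not told apart from a rise after lysolecithin. Vps33a, a gene of vesicle tethering, was 1.59-fold higher than after lysolecithin (SE 0.12; 0.048), and the ribosomal protein-like gene Rpl19l4 1.66-fold (SE 0.13; 0.048).

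Of the 21 release genes 14 were lower after transection than after lysolecithin, with a median of -0.17, and 7 passed as lower when adjusted over the list alone, the others being Vamp1, Vamp2, Rims1 and Sncb (limma fry mixed adjusted p = 0.0312; camera 0.00216, and adjusted p = 0.696 with an estimated correlation). Of the 21 regeneration-associated genes, Ret was 1.45-fold higher than after lysolecithin when adjusted over the list alone. Atf3 and Jun did not pass. Fgf9, Pdgfa (Absent on all 3 transection arrays, at least 1.85-fold) and Fgfr1 were lower than after lysolecithin among 24 growth factor and receptor genes, adjusted over the list alone. On the same terms Col1a1, Col3a1 and Mgp were lower among 10 meningeal and fibroblast genes and Idi1 among 14 cholesterol synthesis genes. So were Acta2 among 7 endothelial and pericyte genes and Ifitm3 among 16 MHC and interferon genes. Ifitm3 was higher after lysolecithin than after saline, as given below. Of these lists, the mixed limma fry test passed for the cholesterol (adjusted p = 0.0422), endothelial (0.0366) and MHC (0.0366) lists, and for the cytoskeletal list (0.0328), in which Ina was the 1 member that fell. None of these 4 passed with camera (adjusted p = 0.402, 0.569, 0.126 and 0.994, and 0.696, 0.813, 0.696 and 0.996 with an estimated correlation). Camera placed the growth factor (adjusted p = 0.0325) and meningeal (0.00798) lists below other genes, each with adjusted p = 0.696 with an estimated correlation. With limma 21 probe sets passed, 4 higher and 17 lower, standing for 16 named genes (2 higher, 14 lower) and 4 probe sets with no symbol, and 598 had an unadjusted p under 0.05. The count was 9 with a pseudocount of 1, 6 from the series value table, and 0 without the detection filter, the intensity trend or the day term or as a difference of differences, in which Rpl19l4, Col1a1 and Mgp turned direction. It was 0 without the lysolecithin day 4 or transection day 10 array, 1 without the lysolecithin day 10 or transection day 4 array, 2 without lysolecithin day 37, 4 without saline day 10 and 11 without transection day 37.

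**Figure D2:**
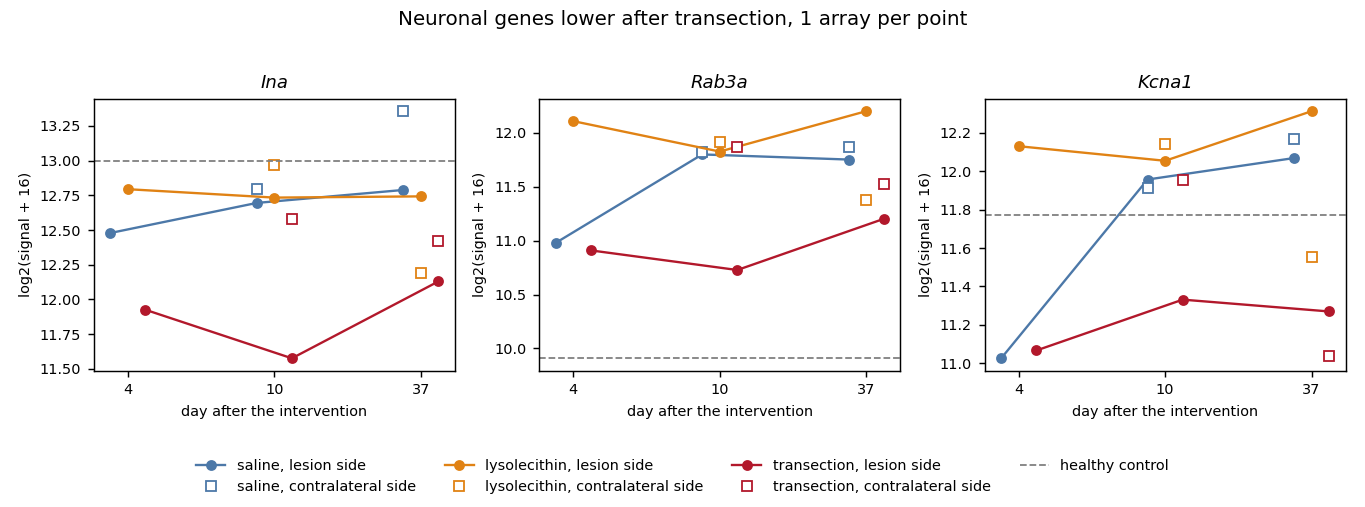
Log2(signal + 16) of Ina, Rab3a and Kcna1 on the 16 arrays against the day after the intervention, with filled circles for lesion-side arrays, open squares for contralateral arrays, a dashed line for the healthy control and 1 array per point. Rab3a stands at 10.9, 10.7 and 11.2 after transection and at 12.1, 11.8 and 12.2 after lysolecithin.

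Lysolecithin and saline were compared on the lesion side to set demyelinated axons against the saline procedure. Immune genes were higher after lysolecithin than after saline: Cd74 rose 3.10-fold (SE of log2 0.20; limma adjusted p = 0.00649; Present on 3 of 3 lysolecithin and 0 of 3 saline arrays, so the size depends on signals near background), the MHC class II chain RT1-Da 2.13-fold (SE 0.17; 0.0358) and C3 at least 1.83-fold (0.0358), each on 3 of 3 days. Of 16 MHC and interferon genes 15 were higher, with a median of 0.37. Of these Cd74, RT1-Da, RT1-Db1 (1.73-fold), Psme1 (1.71-fold) and Ifitm3 (1.66-fold) rose when adjusted over the list alone (limma fry mixed adjusted p = 0.0125; camera 8.07e-05, and adjusted p = 0.696 with an estimated correlation). Of 11 microglial and macrophage genes 9 were higher, with a median of 0.33. Of these Lgals3 (2.44-fold), Lyz2 (1.60-fold), Aif1 (log2 difference 0.58), Cd53 (0.58) and C1qb (1.34-fold) rose when adjusted over the list alone (limma fry mixed adjusted p = 0.0338; camera 0.00916, and adjusted p = 0.696 with an estimated correlation). Among 17 astrocyte genes the intermediate filament Vim (1.99-fold), Slc1a2 (1.93-fold) and Clu (1.31-fold) rose, adjusted over the list alone (limma fry mixed adjusted p = 0.0312; camera 0.0538, and 0.696 with an estimated correlation). Timp1, Present on 1 of 3 lysolecithin and 0 of 3 saline arrays, passed as well, and no size is given for it. Against the 7 controls the medians of these lists were 0.04 (MHC), 0.19 (microglia) and 0.05 (astrocytes) after lysolecithin (limma fry mixed adjusted p = 0.810, 0.755 and 0.599) and -0.33, -0.33 and -0.07 after saline (0.175, 0.593 and 0.0297), with the contralateral arrays described above among these controls.

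Among neuronal genes in this comparison, Syt11 rose 1.92-fold, Syt4 1.61-fold and Cplx1 1.34-fold while Sv2b fell by 0.47 on the log2 scale. Gabrb2 fell by 0.78, Kcnc1 by 0.61, Kcnc2 by 0.53 and Kcnab2 by 0.44, and Thy1 and Egr1 by 0.43 and 0.44, each adjusted over the list alone. Ecel1 (1.99-fold), Bcl2l1 (1.65-fold), the myelin gene Mag (1.32-fold) and the collagen gene Col1a2 (1.63-fold) rose on the same terms. The potassium channel gene Kcnd2 (log2 difference -0.89, SE 0.16) and the cholesterol synthesis gene Fdps (-0.84, SE 0.19) were lower on 3 of 3 days with limma adjusted p of 0.0525 and 0.0871. Respiratory chain genes were lower in 28 of 32 cases, with a median of -0.21 (limma fry mixed adjusted p = 0.0546; camera 0.000363, and adjusted p = 0.696 with an estimated correlation), beside beta-actin 3′/5′ ratios of at most 1.44 after lysolecithin and 1.41 to 1.68 after saline. The receptor list passed the mixed limma fry test (adjusted p = 0.041; camera 0.661, and 0.942 with an estimated correlation). Camera placed the regeneration (adjusted p = 0.0104), growth factor (0.0231) and meningeal (0.00916) lists above other genes, each with adjusted p = 0.696 with an estimated correlation. With limma 7 probe sets passed, 7 higher and 0 lower, standing for 3 named genes and 2 probe sets with no symbol, and 911 had an unadjusted p under 0.05. As a difference of lesion-minus-contralateral differences 0 passed and Cd74 (-1.03), RT1-Da (-1.27), C3 (-0.64), the other MHC and microglial genes named here, Vim, Timp1 and Col1a2 turned to lower values. This alternative leaves out day 4, which has no contralateral arrays, as well as subtracting the contralateral side. The count was 0 without the day term and 1 without the detection filter, the intensity trend or the lysolecithin day 4 array. It was 4 with a filter of 8 Present arrays, 29 with array weights, and 2 and 4 without the saline day 4 and day 10 arrays, 4 without lysolecithin day 37, 17 without transection day 10 and 95 without the saline day 37 array.

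**Figure D3:**
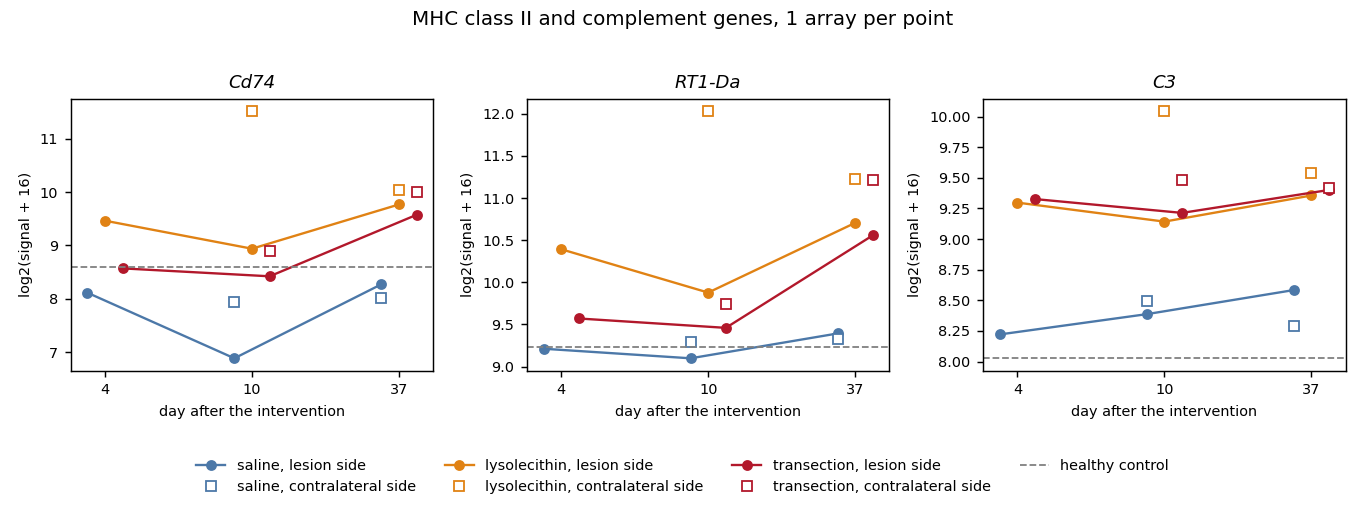
Log2(signal + 16) of Cd74, RT1-Da and C3 on the 16 arrays against the day after the intervention, with filled circles for lesion-side arrays, open squares for contralateral arrays, a dashed line for the healthy control and 1 array per point. The highest Cd74 and RT1-Da values, 11.51 and 12.03, are on the lysolecithin day 10 contralateral array.

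The lesion side was set against the contralateral side in the 6 pairs of days 10 and 37, with the pair as a block. The fit gives a mean over the 3 interventions and does not show that each shared a change. Atf3 was 5.10-fold higher in the transection day 10 pair and 2.83-fold higher in the lysolecithin day 10 pair. On the saline lesion-side arrays it lay within the range of the controls, as given above. The counts of pairs below give direction alone, and whether saline shared these rises was not tested. On the lesion side Atf3 rose 1.96-fold (SE of log2 0.23), Ecel1 1.64-fold (SE 0.18), Gap43 1.46-fold (SE 0.19) and Jun 1.41-fold (SE 0.14) in 6 of 6 pairs and Gadd45a 1.56-fold (SE 0.22) in 5 of 6, adjusted over the 21 regeneration-associated genes alone (camera adjusted p = 0.00916, and 0.696 with an estimated correlation; limma fry mixed adjusted p = 0.142, and directional fry 0.439). Vim (log2 difference -0.58, SE 0.17; lower in 5 of 6 pairs) and Cp (-0.44, SE 0.14; 5 of 6) fell among 17 astrocyte genes (median -0.01; limma fry mixed adjusted p = 0.0117; camera 0.185, and 0.696 with an estimated correlation), and Col1a1 (-0.53, SE 0.14; 6 of 6) among 10 meningeal genes, adjusted over the list alone. Timp1 passed as well, but was called Present on 0 of 6 lesion-side and 3 of 6 contralateral arrays, so no size is given for it. All 11 microglial genes were lower on the lesion side, with a median of -0.25, though 0 passed over the list alone (limma fry mixed adjusted p = 0.306; camera 0.00013, and adjusted p = 0.696 with an estimated correlation). Camera also placed the MHC list lower (adjusted p = 0.00871, and 0.696 with an estimated correlation). The contralateral arrays after lysolecithin and transection were above those after saline on the microglial list, by medians of 0.73 and 0.61. On days 10 and 37 the lesion-minus-contralateral medians of that list were -0.04 and 0.06 after saline, -0.89 and -0.25 after lysolecithin and -0.27 and -0.21 after transection. Tmod1 was at least 1.60-fold higher in 6 of 6 pairs and Sprr1a 1.71-fold higher in 6 of 6 (limma adjusted p 0.826 and 0.851). With limma 0 of 4413 probe sets passed, 219 had an unadjusted p under 0.05, and the count stayed 0 under every other setting and without any single array. The lowest limma adjusted p over all probe sets was 0.826, so no gene named above passed beyond its own list. Pggt1b, 1.78-fold higher here, was lower in the series value table (log2 difference -0.17).

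Between day 4 and day 10 on the lesion side, with the intervention as a term, Vim fell by 1.58 on the log2 scale (SE 0.20; limma adjusted p = 0.0222) and Hspb1 rose 1.96-fold (SE of log2 0.14; 0.0426), each in 3 of 3 interventions. A brighter Hspb1 probe set (rc_AI176658_s_at) pointed the other way, at -0.52, and did not pass. Of 11 microglial and macrophage genes 10 were lower, with a median of -0.38, and Ptprc (at least 2.40-fold), Aif1 (-0.73), Lgals3 (-0.69), Lyz2 (-0.58) and C1qb (-0.50) fell when adjusted over the list alone (limma fry mixed adjusted p = 0.0125; camera 0.000171, and adjusted p = 0.696 with an estimated correlation). Of 32 respiratory chain genes 25 were lower, with a median of -0.18, and Ndufa6 (-0.55), Cox5b (-0.45), Ndufb2 (-0.42), Atp5po (-0.41) and Ndufb8 (-0.35) fell on the same terms (limma fry mixed adjusted p = 0.0312; camera 0.000171, and adjusted p = 0.696 with an estimated correlation). The beta-actin 3′/5′ ratio was lower on day 10 (1.08 to 1.41) than on day 4 (1.42 to 1.68) in 3 of 3 interventions, and that of GAPDH in 1 of 3. The ferroxidase Cp (-0.80) fell among astrocyte genes (limma fry mixed adjusted p = 0.0328; camera 0.593, and 0.813 with an estimated correlation), and the NMDA receptor subunit Grin1 (1.65-fold) and Fgfr2 (at least 1.53-fold) rose, each adjusted over the list alone. With limma 2 probe sets passed and 581 had an unadjusted p under 0.05. The count was 0 without the detection filter, without the intervention term and without the day 4 or day 10 array of lysolecithin or of transection. It was 1 with quantile normalization, without the intensity trend, from the series value table or without the saline day 4, lysolecithin day 37 or transection day 37 array, 4 with array weights or without saline day 10 and 5 without saline day 37.

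Between day 4 and day 37, Vim fell by 1.74 on the log2 scale (SE 0.20; limma adjusted p = 0.00819; lower in 3 of 3 interventions). Adjusted over the list alone, S100a10 (-0.85) and Cp (-0.77) fell and Slc1a2 rose 1.43-fold among astrocyte genes, Lgals3 (-0.97), C1qb (-0.55) and Spp1 (-0.33) fell among microglial genes, and Ddit3 fell by 1.26 on the log2 scale (SE 0.28). The activity-regulated genes Nr4a1 (1.55-fold), Fos (1.51-fold) and Arc (1.34-fold) rose among 15 immediate early genes, as did Grin1 (1.58-fold) and Mag (1.41-fold), and Kcnc2 fell by 0.62, on the same terms. The mixed limma fry test passed for the microglial and astrocyte lists (adjusted p = 0.0162 for both), the MHC list (0.0312), the respiratory chain list (0.0312), the stress list (0.0366; median 0.03, mean -0.05) and the oligodendrocyte list (0.041; median -0.00, mean 0.01). The stress call ended with quantile normalization (limma fry mixed adjusted p = 0.166) and with the mean of all probe sets of a gene (0.194), and the respiratory chain call with the latter (0.104). The beta-actin 3′/5′ ratio was lower on day 37 (1.07 to 1.43) than on day 4 (1.42 to 1.68) in 3 of 3 interventions, and that of GAPDH in 1 of 3. With camera the microglial (adjusted p = 0.00871), astrocyte (0.0279) and endothelial (0.0462) lists were lower on day 37, each with adjusted p = 0.696 with an estimated correlation. The MHC, respiratory chain, stress and oligodendrocyte lists did not pass with camera (adjusted p = 0.142, 0.292, 0.822 and 0.986, and 0.696, 0.912, 0.951 and 0.996 with an estimated correlation). With limma 1 probe set passed and 723 had an unadjusted p under 0.05. The count was 0 without the detection filter, the intensity trend or the intervention term or without the lysolecithin day 4 or day 37 array, 2 with quantile normalization or without the transection day 4 or day 10 array, 5 from the series value table and 21 without the saline day 37 array.

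Between day 10 and day 37, Ecel1 (log2 difference -1.15, SE 0.25), Atf3 (-1.34, SE 0.37) and Gap43 (-0.71, SE 0.19) fell when adjusted over the 21 regeneration-associated genes alone, Atf3 in 2 of 3 interventions and the others in 3 of 3. RT1-Da rose 1.67-fold among MHC genes (limma fry mixed adjusted p = 0.0312; camera 0.00975, and adjusted p = 0.696 with an estimated correlation) when adjusted over the list alone. The microglial list passed the mixed test (limma fry mixed adjusted p = 0.0312; camera 0.392, and 0.765 with an estimated correlation). Its 1 member past the threshold over the list alone, Ptprc, was called Present on 0 of these 6 arrays and is not counted as a rise. Trh (-1.56, SE 0.32) and Adcyap1 (-1.35, SE 0.26) were lower in 3 of 3 interventions with limma adjusted p of 0.349 and 0.339. Camera placed the regeneration list lower (adjusted p = 0.00872) and the respiratory chain list higher (0.00125) on day 37, both with adjusted p = 0.696 with an estimated correlation. With limma the lowest adjusted p over all probe sets was 0.315, 0 probe sets passed and 346 had an unadjusted p under 0.05. The count was 2 with both sides of days 10 and 37 in the fit and 17 without the saline day 37 array.

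Single pairs of arrays were described without a test, since each had 1 array per arm. Against its own contralateral array, transection on day 10 had 150 of 4413 probe sets at 2-fold or more, among them the unfolded-protein kinase Eif2ak3 (7.83-fold), Gadd45a (6.19-fold, and 4.06-fold for another probe set), Atf3 (5.10-fold), Adcyap1 (4.46-fold) and Trh (4.01-fold), with Lyz2 and Vamp1 at log2 ratios of -1.44 and -1.19. Transection on day 37 had 62 such probe sets, with Pip4p1 at a log2 ratio of 1.58, Trappc3 at 1.08 and the lysosomal gene Psap at 2.09-fold, and with Ppp1cb (S78218_g_at) at -1.79, Vim at -1.48 and 1 probe set of Gadd45a (rc_AI070295_at) at -1.33, where the others named here were at 0.24 and 0.20. The same Ppp1cb probe set was at 2.11 after saline and at -2.04 after lysolecithin on day 37. Lysolecithin on day 10 had 97, with Gadd45a at 3.46-fold (rc_AI070295_at, beside 3.30-fold and 1.76-fold for its other probe sets), Atf3 at 2.83-fold and Ecel1 at 2.64-fold on the lesion side. In that pair Cd74, RT1-Da and the Fc receptor gene Fcgr2b were at log2 ratios of -2.57, -2.15 and -1.39. On day 37 lysolecithin had 81, 33 higher and 48 lower, with Gstm1 at 2.23-fold and Fgf9 at 2.13-fold, and with Marcks and Slc24a2 at log2 ratios of -1.79 and -1.35. Saline had 33 on day 10 and 92 on day 37. Of the 92, 67 were higher and 25 lower, with Pcmtd2 at a log2 ratio of 1.45, Aqp4 at -1.64 and Map2 at -1.39. Day 4 had no contralateral array, and against the healthy control saline, lysolecithin and transection had 658, 355 and 588 such probe sets. These 3 pairs correlated at r = 0.914, 0.938 and 0.917, beside 0.971 to 0.988 for the lesion and contralateral pairs. Their counts cannot be set beside those of days 10 and 37, since the shared healthy array correlated least with the others. In the same order, saline included, Ywhaz was 19.3-fold, 19.1-fold and 11.1-fold higher and another Ppp1cb probe set (S78218_at) 15.9-fold, 14.1-fold and 16.3-fold. Microglial genes were at median log2 ratios of 0.93, 1.38 and 1.06 in these 3 day 4 pairs, which share the 1 healthy array, itself at a median of -0.68 against the contralateral arrays on this list. The median of the release genes after transection on day 10 was -0.38, below all 10000 random lists of matched expression, and that of the regeneration-associated genes was 0.34, above all 10000. These percentiles describe those arrays alone and are no test, since random lists ignore correlation between genes. Placements of the other lists and pairs are not given here.

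Over all 20 lists and 10 comparisons, 35 of 200 mixed tests and 0 of 200 directional rotation tests passed after adjustment, with 27 directional tests at an unadjusted p under 0.05. Of the 35, 33 passed with quantile normalization, 33 with the mean of all probe sets of a gene and 32 with both. Camera with a preset correlation passed 31, 15 higher and 16 lower, and camera with an estimated correlation passed 0, its lowest adjusted p being 0.696. Among cell type lists not named above, GABA and glycine neurons (5 genes) and oligodendrocyte precursors (5 genes) passed in 0 comparisons, as did immediate early genes (15) and voltage-gated ion channels (19) in the mixed test.

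**Figure D4:**
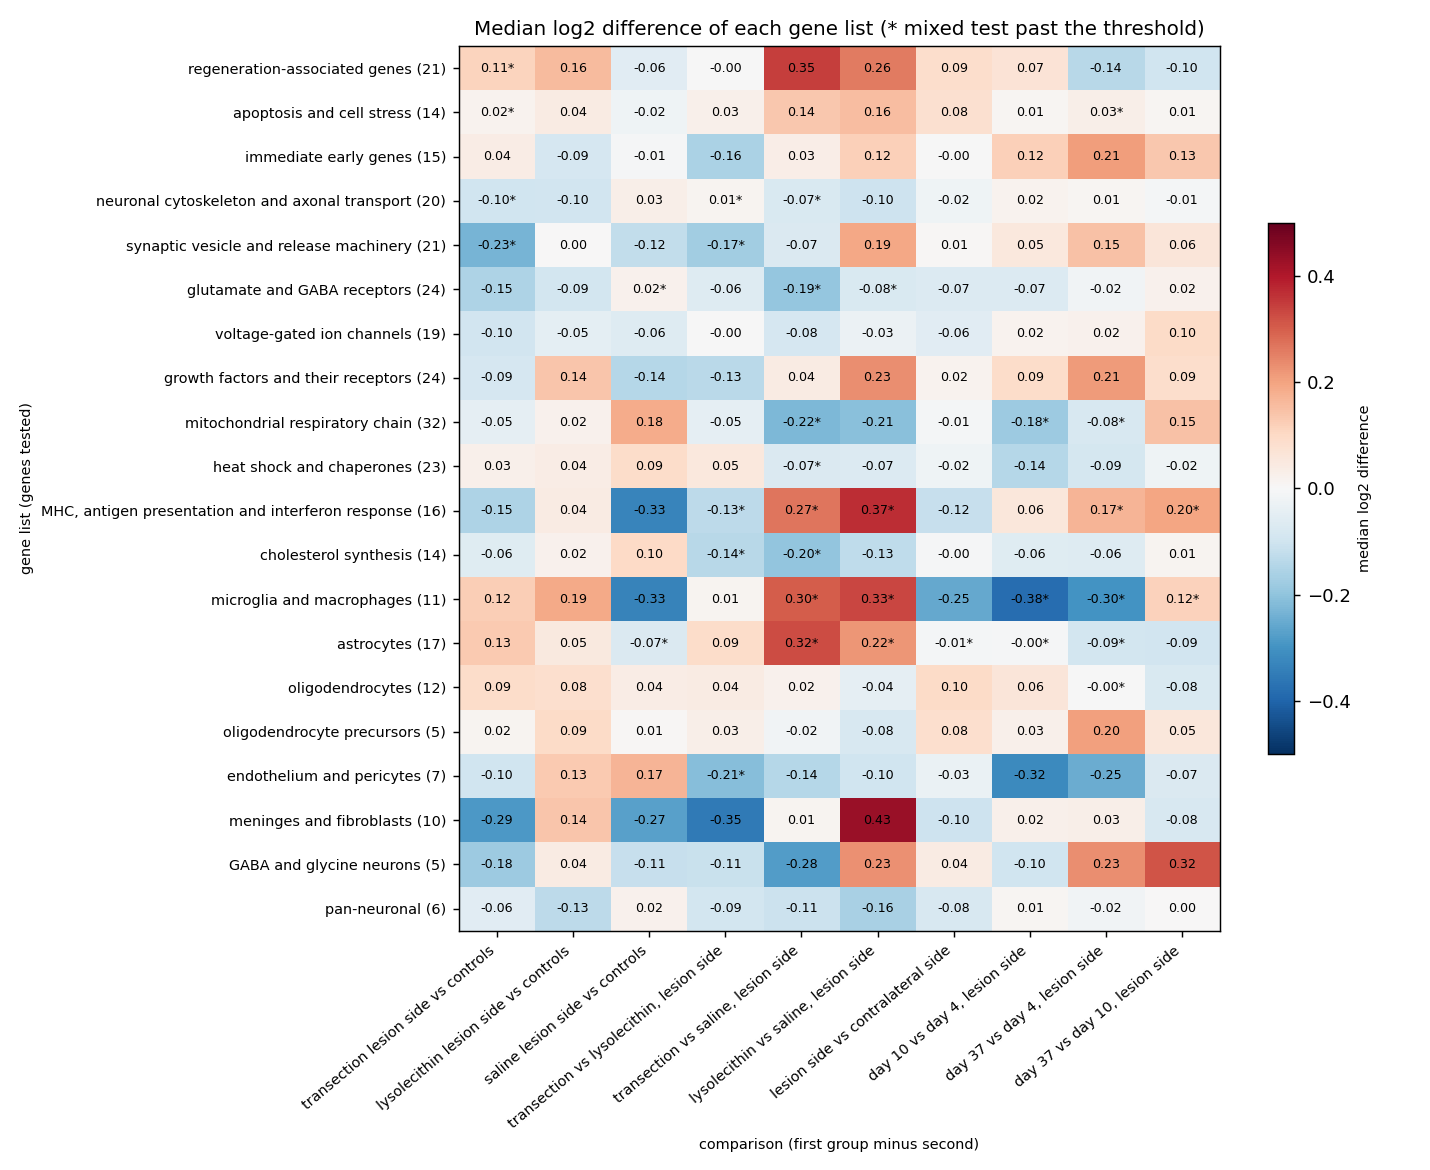
Median log2 difference of the 20 gene lists (rows, genes tested in brackets) in the 10 comparisons (columns), coloured from blue (lower in the first group named) to red (higher), with an asterisk where the mixed rotation test passed. The microglial list has a median of -0.38 between day 4 and day 10 and of 0.33 for lysolecithin against saline.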

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

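The tests of exchanged labels, of a contralateral response and of degraded RNA were chosen only after the result was seen. Among the 7 control arrays, 39 measures were searched for an array far from the others and 6 were found, where chance gives about 1 in 20, or 1.95. The healthy control had a mean correlation with the other arrays of 0.938, beside 0.969 to 0.974 for the contralateral arrays. On the transection day 10 contralateral array Adcyap1 and Ecel1 were high, both at a log2 signal of 9.90, beside at most 9.39 and 9.22 on the others, and Ino80e was low, at 9.02 beside at least 9.37. Nup58 was low on the saline day 37 contralateral array, at 5.45 beside at least 6.66. Kctd13 was low on the lysolecithin day 37 contralateral array, at 12.6 beside at least 13.8.

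Differences between interventions were found on the lesion side: 21 probe sets for transection against lysolecithin, 32 for transection against saline and 7 for lysolecithin against saline. Each of these comparisons has 10 splits of its 6 arrays, too few for a share under 0.05, with at most 1 probe set in another split for each. The same limit holds for day 10 against day 4 (2 probe sets, highest other 1), day 37 against day 4 (1, highest other 0) and day 37 against day 10 (0, highest other 0, with 10 of 10 splits giving as many, as a count of 0 requires). For transection against the controls, chance cannot be excluded: 12 of 100 splits gave at least its 1 probe set (highest other 13). Which arrays carried the split with 13 was not tested. Where the real count is 0, every split gives at least as many, so the splits decide nothing: 100 of 100 for lysolecithin (highest other 7) and for saline (highest other 10) against the controls, and 32 of 32 for the 6 pairs (highest other 0). In limma the comparisons with 0 had 205 (lysolecithin), 549 (saline), 219 (sides) and 346 (day 37 against day 10) probe sets at an unadjusted p under 0.05. Chance alone gives a share of about 0.05 of the 4413 tested probe sets, which the counts for lysolecithin and for the sides do not exceed. The counts for saline and for day 37 against day 10 do, though probe sets on an array are not independent.

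MHC class II genes were higher on the lysolecithin than on the saline contralateral arrays: Cd74 7.02-fold, RT1-Da 4.99-fold, RT1-Db1 2.14-fold, RT1-Ba 1.81-fold, RT1-Bb 1.74-fold, RT1-DMb 1.67-fold and RT1-DMa 1.28-fold, as means of 2 arrays each. RT1-Db1, RT1-Ba and RT1-DMb were called Present on 0 of the 2 saline arrays, so their sizes rest on signals near background. The Cd74 probe set used here (X13044_at) was Present on 2 of 2 arrays of each group. The Cd74 ratio given for the lysolecithin day 10 pair is from another probe set (X13044_g_at). For an exchange of the sides on the lysolecithin day 10 labels, 5 of 5 injury genes were higher on the array labelled lesion side, although Sprr1a differed by only 0.05. These genes were chosen after the result was seen, and Atf3, Ecel1 and Gadd45a were among the highest of this pair. The count therefore cannot decide the question. More meningeal and vascular tissue together is argued against by the endothelial list of 7 genes, with a median of -0.30 (value -0.295). The meningeal list had a median of 0.31 with 9 of 10 members higher, so more meningeal tissue alone stays open. More microglia or macrophages in the tissue sampled has the values it needs, a list median of 0.73 with 90.9% of its 11 members higher (C1qb by 1.28 on the log2 scale, Aif1 by 0.73, Lyz2 by 0.48), so it may account for the pattern. Resident microglia also express these genes. A response of the contralateral side to lysolecithin stays open, since there is 1 healthy array.

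The healthy control array correlated least with the others. Degraded RNA stays open, since the 2 ratios point apart: its beta-actin 3′/5′ ratio of 1.04 was the lowest, beside 1.07 to 1.68 on the others, and its GAPDH ratio of 1.26 the highest, beside 1.03 to 1.23. The scaling of the array is argued against by a mean correlation of 0.938 after quantile normalization, beside 0.963 to 0.978. Other tissue or cell types in the dissected piece stay open: among 12 cell type lists the largest median difference from the contralateral arrays was -0.68 (value -0.677), for microglia and macrophages. No biological explanation was tested.

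One probe set named Kctd13 was far lower on the saline lesion-side arrays (log2 signal 9.56) than on the controls (14.0). An artefact of this probe set has the values it needs: the other probe sets differed by -0.06 and -0.295 on the log2 scale, so the transcript itself may not have changed. The probe set was also low on the lysolecithin day 37 lesion-side array, at 10.00 beside 13.7 and 14.0 on the other lysolecithin lesion-side arrays. An effect of the saline intervention stays open, as untested.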

How the results depend on the processing

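All alternatives here were planned; for each changed count below the cause was not tested. Transection against controls gave 1 probe set, 0 without the detection filter, without the intensity trend, against contralateral arrays only or against its own contralateral arrays in pairs, 2 on days 10 and 37, 6 from the series value table and 0 to 64 with an array left out. Lysolecithin against controls stayed at 0. Saline against controls gave 0, 4 with array weights, 2 from the value table and 0 to 1 with an array left out. Transection against lysolecithin gave 21, 9 with a pseudocount of 1, 6 from the value table, 0 without the filter, trend or day term or as a difference of lesion-minus-contralateral differences, and 0 to 31 with an array left out. Transection against saline gave 32, 14 with quantile normalization, 0 in the same 4 settings and 0 to 56. Lysolecithin against saline gave 7, 1 without the filter or trend, 4 with Present calls on 8 arrays, 29 with array weights, 0 without the day term or as differences, and 1 to 95. The side comparison stayed at 0. Day 10 against day 4 gave 2, 1 with quantile normalization, without the trend or from the value table, 0 without the filter or intervention term, 4 with array weights and 0 to 5. Day 37 against day 4 gave 1, 2 with quantile normalization, 5 from the value table, 0 without the filter, trend or intervention term and 0 to 21. Day 37 against day 10 gave 0, 2 with both sides and 0 to 17.

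As a difference of differences these log2 values reversed: in transection against lysolecithin Rpl19l4 to -0.00109, Col1a1 to 0.32 and Mgp to 0.26. In transection against saline they were Hspb1 -0.41, Cd74 -0.0505, C3 -0.24, Psme1 -0.35, Lgals3 -0.33, RT1-Da -0.40, Cd53 -0.0280 and Timp1 -0.0390. In lysolecithin against saline they were Timp1 -0.54, Cd74 -1.03, Lgals3 -0.47, RT1-Da -1.27, Col1a1 -0.19, C3 -0.64, Psme1 -0.16, Cd53 -0.50, Aif1 -0.33, RT1-Db1 -0.46, Ifitm3 -0.41, Vim -0.78, C1qb -0.87, Col1a2 -0.39 and Lyz2 -0.10. In the side comparison Pggt1b went to -0.17 in the value table.

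With a pseudocount of 64 the probe sets at 2-fold or more on days 4 (against the healthy control), 10 and 37 numbered 507, 9 and 35 for saline, 263, 48 and 37 for lysolecithin and 459, 80 and 23 for transection. With quantile normalization saline day 37 gave 71 and transection day 10 121. Camera with a preset correlation passed 31 list tests.

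Among the named genes, 2118 values in other settings kept direction and side of the threshold, 195 lost and 23 gained it, and 27 reversed. With an array left out the numbers were 2244, 252, 68 and 0. Most of these values had not passed in the main fit, so staying on that side was the likely outcome. The totals therefore say little about how stable the calls are, which the next counts describe. Of 40 named values past the threshold, 40 passed with a pseudocount of 64, 37 with array weights, 32 with a pseudocount of 1, 28 with quantile normalization, 19 from the value table and 0 without the filter or without the trend. With a lesion-side array left out, 0, 7 and 20 passed without lysolecithin day 4, 10 and 37, 5, 4 and 23 without those of transection and 14, 8 and 34 without those of saline. Without the filter 8740 probe sets enter the adjustment. With an array left out of a group of 3, limma takes the spread from all groups together. Dim probe sets limit what can be compared: at most 47.1% were Present on an array.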

Other observations

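Contralateral values differed between interventions, in genes chosen after their values were seen. Complement C1qb was 2.43-fold higher, and Vim 2.63-fold, on the lysolecithin than on the saline contralateral arrays, as means of 2 arrays each and without a test. C3 was called Present on 2 of 2 of the former and 0 of 2 of the latter. After transection the contralateral microglial list was higher than after saline by a median of 0.61, with 11 of 11 members higher, and the MHC list by 0.33, with 15 of 16 higher.

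Relative to the 6 contralateral arrays, the healthy control had a median of -0.31 for the MHC list and 0.42 for the 5 genes of GABA and glycine neurons, with 1 array and no test. Adcyap1, Ecel1 and Trh on the transection day 10 contralateral array, at log2 signals of 9.90, 9.90 and 10.5, were the highest among the controls.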
